A study of Oryza sativa with 12 samples.

How the data were processed

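Poly-A RNA of rice (Oryza sativa) roots was sequenced in 12 libraries, 3 in each of 4 groups. Roots were untreated, or held for 72 hours with 0.1 mM spermidine, with 100 mM NaCl, or with both, per the labels. The labels give no time for the untreated roots, so comparisons with them may include a difference in time. Spermidine is a polyamine, a small positively charged molecule that plant cells also make themselves. The labels number the libraries of each group but do not say whether they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

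A single deposited table holds FPKM (fragments per kilobase of transcript, scaled to the reads of the library) for 182689 unigenes, which are clusters of assembled transcripts, with the best protein hit of each in several databases. Per the submitters' processing notes, CASAVA 1.8, Bowtie2 and RSEM were used; their roles, the way the transcripts were assembled and any filter are not given in the sources used here. A unigene is not a gene: several unigenes can stand for the same gene, their descriptions come from the best protein hit, which can be of another species, and reads shared between near-identical unigenes make such values uncertain. No genome was used here, so no positions are given. All columns of the table belonged to the 12 libraries.

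The deposited FPKM values summed to between 1312574 and 1371599 per library. FPKM keeps no read counts, so total depth is unknown and no counting intervals are given. Low values gave the relative depth of the libraries, which ran from 0.925 to 1.08. Between 101814 and 125638 unigenes were above 0 in a library. A value of exactly 0 is given as listed at 0, since it can be a failed estimate.

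Values were tested as log2(FPKM + 1) for the 65836 unigenes with a mean of at least 1 FPKM over all libraries. A fold change on this scale understates the change of low unigenes. limma 3.58.1 in R 4.3.3 fitted 4 group means to all libraries together, with empirical Bayes variances that follow the mean, and gave 5 comparisons between groups and the interaction, which is the change with spermidine under NaCl minus the change with spermidine without NaCl. Tests were two-sided, with Benjamini-Hochberg adjustment over unigenes within each comparison and calls at an adjusted p below 0.05. Errors of means are SD over 3 libraries and errors of log2 changes are SE.

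For gene groups, 37 lists were defined by words in the protein descriptions. They were tested with camera (limma) at a preset correlation of 0.01 between members, with adjustment over the lists. camera compares the members with all other unigenes, and an estimated correlation was used beside the preset value. fry asks whether the members move, on balance, in a single direction. It does not compare them with other unigenes, so a shift of all values can also give a call, and it was not run with other scalings. Lists included markers of shoot tissue, RNA quality and root cell types. The RNA quality list, called organelle-encoded genes, also takes in descriptions of ribosomal proteins of organelles, which the ribosomal protein list matches too. Which of its members are encoded in organelles was not checked. Unigenes whose best hit was recognised by name as not a plant were kept out of the lists. The rule for named genes took, in the first 3 comparisons and the interaction, the 6 largest rises and 6 largest falls among called unigenes with a mean of at least 5 FPKM in a group compared, no overlap between the groups and an informative description, each description spelled the same way counting once. For the interaction, overlap between groups was not tested. The rule also took up to 2 called members per direction and list, the list's most abundant member where none was called, the polyamine members with a mean of at least 10 FPKM, the HKT, SOS1 and NHX sodium transporters with a mean of at least 5 FPKM and any unigene described as bZIP73, which the title of the series names. No unigene had that description (0 found), so bZIP73 is not analysed here. The genes named in the text are a part of those the rule gave, picked after the values were seen.

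The samples, tests, lists, naming rule and main alternatives were fixed before the data were examined. The table held many hits to other organisms, so the unigenes were then sorted into 4 classes by best hit: Oryza (43487 of those tested), other plants including green algae (4871), organisms that are not plants (2509) and no hit (14969). Organisms that are not plants were recognised from a list of organism names. Every other hit outside Oryza was counted as another plant, so that class can hold unlisted organisms that are not plants. This sorting, the analyses limited to unigenes with an Oryza hit and the naming of the largest changes among Oryza hits were chosen after seeing the data. The unigenes with an Oryza hit are called rice-hit unigenes.

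The same steps were tested on simulated data with the means and empirical Bayes variances of the real unigenes and 50 changed unigenes per size of change. With the changed unigenes drawn from the rice hits and 65836 unigenes in the fit, NaCl against untreated recovered 10% of those changed by 0.5 on the log2 scale, 30% at 1, 76% at 2 and 98% at 4, with 2 false calls. For spermidine against untreated the shares were 0%, 30%, 76% and 92%, with 7 false calls, and for spermidine+NaCl against NaCl 4%, 40%, 82% and 88%, with 4. Each run changed fewer unigenes than the 15083, 1682 and 10403 called in the real comparisons of NaCl, spermidine and spermidine+NaCl against NaCl. The adjustment is stricter when few unigenes change, so these shares do not give the recovery in the real data. In the NaCl comparison, camera called 1 list after a shift of 0.5 was given to the WRKY list, which was the list shifted. The simulated unigenes varied independently, while the real WRKY members had an estimated correlation of 0.129. The run therefore does not show how often camera calls unshifted lists in the real data.

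Comparisons that share libraries were set beside 20 simulations of unchanged groups and beside the overlap of independent lists of the same sizes. Alternatives were a smaller pseudocount, other filters on low values, median-ratio scaling, quantile normalization, variances without a trend, array weights, the replicate number as a block, only the groups compared in the fit, a minimum fold change, FPKM summed per protein, plant hits alone, and each library left out in turn. Tools made for read counts were not applicable to FPKM. Other splits of the samples were refitted, at most 100 per result. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.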

Results

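The 4 groups of rice roots were compared for the response to salt, to spermidine, and to spermidine under salt, the question named in the title of the series. Each group had 3 libraries. Within groups, the correlation of log2 values between libraries was 0.877 to 0.902 in untreated roots, 0.85 to 0.868 with spermidine, 0.928 to 0.929 with NaCl and 0.86 to 0.901 with spermidine+NaCl. Rice-hit unigenes held 79.7% ± 2.5 (SD, n = 3) of the FPKM in untreated roots, 78.3% ± 2.1 with spermidine, 84% ± 0.52 with NaCl and 81.5% ± 1.4 with both. Unigenes whose best hit was not a plant held 1.13% ± 0.45, 1.56% ± 0.46, 0.562% ± 0.033 and 0.878% ± 0.56 in the same order. Among rice-hit unigenes, the first principal component (46.9% of the variance) placed the NaCl libraries at 119.1 to 137.5 and every other library at or below 17.7.

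**Figure D1:**
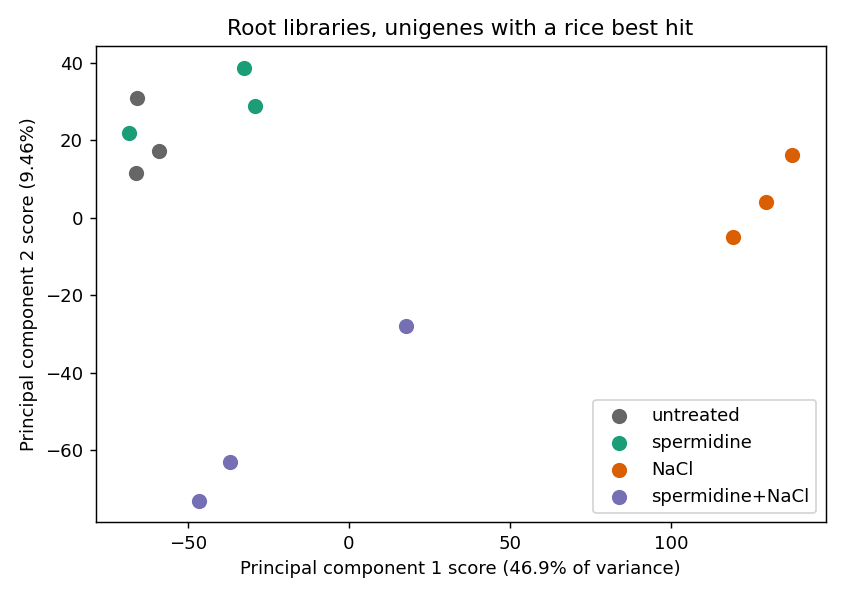
Scores of the 12 root libraries on principal components 1 (46.9% of the variance) and 2 (9.46%) of log2(FPKM + 1) over rice-hit unigenes, each point a library coloured by treatment. The NaCl libraries lie at 119.1 or more on component 1, and the spermidine+NaCl libraries lie at or below 17.7 there and lowest on component 2.

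The largest rises with salt alone, by the rule for named genes, were in transcription factors. A unigene described as ERF109, an ethylene-response factor, went from 0.643 ± 0.716 FPKM (SD, n = 3) in untreated roots to 1290 ± 316 with NaCl, a log2 change of 9.67 ± 1.46 (SE; adjusted p = 0.000921). The basic helix-loop-helix factor bHLH35 rose from 1.12 ± 0.0436 to 612 ± 102 FPKM, WRKY71 from 4.13 ± 0.191 to 687 ± 79.9 and ERF110 from 0.46 ± 0.272 to 231 ± 37.6. The cold- and drought-response factor DREB1C, named after its values were seen, rose from 0.357 ± 0.309 to 207 ± 90.3 FPKM. In the opposite direction, RAP2-13, another member of the AP2/ERF family, fell from 748 ± 22.9 to 174 ± 8.78 FPKM, and GLUTAMINE DUMPER 2, an amino acid export regulator also named after its values were seen, fell from 74 ± 7.5 to 5.84 ± 1.22.

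Some lists of regulators and defence genes moved up and others did not. bZIP factors had 16 higher and 35 lower of 136, MYB factors 52 and 57 of 273, and diterpenoid phytoalexin genes 5 and 10 of 38. camera called none of these (adjusted p = 0.141, 0.969 and 0.969), while fry called each downward (adjusted p = 0.000412, 0.00864 and 0.0354). Their median log2 changes were -0.27, -0.15 and -0.09, against -0.129 over all unigenes. The fry calls of the MYB and phytoalexin lists may therefore only reflect the common shift. Of 160 WRKY unigenes, 83 were called higher and 14 lower (87 and 20 adjusted over the list alone), with a median log2 change of 0.94 (camera adjusted p = 6.68e-14; adjusted p = 0.228 with an estimated correlation). Among 125 jasmonate unigenes, 57 rose and 18 fell (59 and 22 adjusted over the list alone; camera adjusted p = 5.43e-09; adjusted p = 0.118 with an estimated correlation). Lipoxygenase 5, of the enzyme family that starts jasmonate synthesis, rose from 4.99 ± 1.22 to 259 ± 39.7 FPKM, and TIFY 6b, a jasmonate-signalling repressor, from 23.8 ± 1.72 to 92.5 ± 1.43. The AP2/ERF and DREB list had 82 higher and 39 lower of 220 (91 and 45 adjusted over the list alone; camera adjusted p = 8.19e-06; adjusted p = 0.248 with an estimated correlation). Pathogenesis-related proteins and chitinases had 98 higher and 35 lower of 354 (105 and 41 adjusted over the list alone; camera adjusted p = 4.99e-06; adjusted p = 0.0518 with an estimated correlation), with germin-like protein 2-1 going from 0.0933 ± 0.162 to 59.1 ± 11.5 FPKM.

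Cell wall and detoxification lists also had more members called higher than lower under salt. Lignin and phenylpropanoid synthesis had 87 higher and 32 lower of 231 (92 and 38 adjusted over the list alone; camera adjusted p = 5.43e-09; adjusted p = 0.118 with an estimated correlation), and a phenylalanine ammonia-lyase, the entry enzyme of that pathway, rose from 96.2 ± 4.17 to 472 ± 39.6 FPKM. Expansins and other wall-loosening proteins had 65 higher and 25 lower of 169 (72 and 30 adjusted over the list alone; camera adjusted p = 4.98e-06; adjusted p = 0.248 with an estimated correlation). Within it, xyloglucan endotransglucosylase/hydrolase 2 rose from 2.72 ± 1.4 to 196 ± 38.2 FPKM while Expansin-B7 fell from 253 ± 58.1 to 47.7 ± 3.63. Glutathione S-transferases had 37 higher and 7 lower of 128 (42 and 10 adjusted over the list alone; camera adjusted p = 1.34e-05; adjusted p = 0.248 with an estimated correlation). Cellulose and pectin genes had 51 higher and 28 lower of 257 (58 and 32 adjusted over the list alone; camera adjusted p = 0.000917; adjusted p = 0.248 with an estimated correlation), among them COBRA-like protein 4, known from cellulose deposition, at 0.3 ± 0.221 FPKM untreated and 23.6 ± 2.63 with NaCl. Class III peroxidases had 79 higher and 49 lower of 352 (86 and 53 adjusted over the list alone; camera adjusted p = 0.00585, and 0.111 after quantile normalization; adjusted p = 0.248 with an estimated correlation).

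Among protective and hormone genes, some lists were called and single members changed strongly. The osmolyte list had 30 higher and 13 lower of 118 (33 and 20 adjusted over the list alone; camera adjusted p = 0.0178, and 0.0501 after quantile normalization; adjusted p = 0.229 with an estimated correlation), and trehalose-phosphate phosphatase 1 rose from 5.82 ± 0.556 to 177 ± 26.6 FPKM. LEA proteins and dehydrins, which protect cells during water loss, had 7 higher and 1 lower of 20 (8 and 3 adjusted over the list alone; camera adjusted p = 0.0211, and 0.0816 after quantile normalization; adjusted p = 0.469 with an estimated correlation). SENESCENCE-ASSOCIATED GENE 21 of that list rose from 15.3 ± 3.3 to 145 ± 34.6 FPKM. NAC factors had 47 higher and 31 lower of 180 (52 and 40 adjusted over the list alone), with a mean log2 change of 0.38, a median of -0.04 that turned to 0.08 with median-ratio scaling, and a test upward (camera adjusted p = 0.0223; adjusted p = 0.275 with an estimated correlation). The abscisic acid list was not called (camera upward, adjusted p = 0.158; mean log2 change 0.28, median -0.1), with 25 higher and 17 lower of 87 (25 and 21 adjusted over the list alone). NCED4, which makes an abscisic acid precursor, rose from 0.153 ± 0.153 to 23.3 ± 1.73 FPKM, and the abscisic acid receptor described as PYL5 fell from 102 ± 7.87 to 23.7 ± 3.3.

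More iron genes were called lower than higher with salt. Of 111 unigenes of iron acquisition and storage, 56 were lower and 3 higher (59 and 6 adjusted over the list alone), with a median log2 change of -0.63 (camera adjusted p = 1.95e-06; adjusted p = 0.248 with an estimated correlation). A unigene described as IRO2, a regulator of iron uptake, fell from 19.4 ± 0.438 to 1.15 ± 0.438 FPKM; its best hit was to another plant. Cell cycle and DNA replication genes had 58 lower and 9 higher of 314 (56 and 9 adjusted over the list alone; camera adjusted p = 0.0148; adjusted p = 0.554 with an estimated correlation), with histone H1 falling from 295 ± 25.3 to 87.4 ± 3.3 FPKM. Markers of shoot tissue had 4 higher and 2 lower of 39 (3 and 2 adjusted over the list alone; camera adjusted p = 0.0411, and 0.0829 with median-ratio scaling; adjusted p = 0.761 with an estimated correlation). Organelle-encoded genes, a check of RNA quality, had 25 lower and 0 higher of 165 (21 and 0 adjusted over the list alone; camera adjusted p = 0.111, and 0.0351 after quantile normalization, both downward).

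Ion and polyamine genes changed in both directions. Among 102 sodium and potassium transport unigenes, 8 rose and 15 fell, the same numbers adjusted over the list alone. Potassium transporter HAK7 rose from 0.477 ± 0.176 to 7.43 ± 1.39 FPKM and the potassium channel AKT1 fell from 285 ± 16.7 to 126 ± 14.5. The sodium transporter HKT8 went from 25.4 ± 7.84 to 14 ± 0.877 FPKM (log2 change -0.78 ± 0.2, adjusted p = 0.017), a call lost without NaCl replicate 3 (adjusted p = 0.0554) or with only the groups compared in the fit. Of 73 polyamine unigenes, 19 rose and 22 fell (20 and 24 adjusted over the list alone). Arginine decarboxylase 1 rose from 97.5 ± 7.4 to 184 ± 8.08 FPKM, ornithine decarboxylase from 4.41 ± 1.4 to 23.9 ± 2.22 and a unigene described as S-adenosylmethionine decarboxylase from 67.5 ± 4.8 to 274 ± 17.1, 3 enzymes of polyamine synthesis. Of other unigenes described as S-adenosylmethionine decarboxylase, 1 rose from 96.6 ± 4.35 to 363 ± 30.9 FPKM and another from 13.3 ± 2.2 to 30.3 ± 3.67. Others were at 126 ± 8.19 and 101 ± 12.9 (adjusted p = 0.0501, and 0.0394 in the fit of rice hits alone and 0.00989 after quantile normalization) and at 17.2 ± 0.58 and 17.2 ± 0.397. The remaining one went from 173 ± 6.06 to 143 ± 8.44 FPKM (adjusted p = 0.0281). This call was lost with median-ratio scaling (0.19) and without replicate 1 or 3 of NaCl or of untreated roots (highest adjusted p = 0.105, without NaCl replicate 1). Spermidine synthase 1 was at 85.8 ± 6.11 and 91 ± 7.47 FPKM (adjusted p = 0.545). A unigene of polyamine oxidase 2 rose from 16.3 ± 0.934 to 53 ± 2.89 FPKM and another from 33.6 ± 1.87 to 52.8 ± 1.06. A further unigene of that name was at 14.5 ± 5.75 and 13.4 ± 4.72 (adjusted p = 0.942). Polyamine oxidase 4 fell from 8.02 ± 1.1 to 1.84 ± 0.0814 FPKM in a minor unigene and from 363 ± 29.3 to 220 ± 9.99 in a more abundant one. Unigenes described as putrescine hydroxycinnamoyltransferase 3, which joins putrescine to phenolic acids, went in opposite directions. Of these, 1 rose from 11.4 ± 2.48 to 116 ± 2.55 FPKM and another fell from 18.6 ± 6.91 to 4.28 ± 2.29 (adjusted p = 0.0108).

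**Figure D2:**
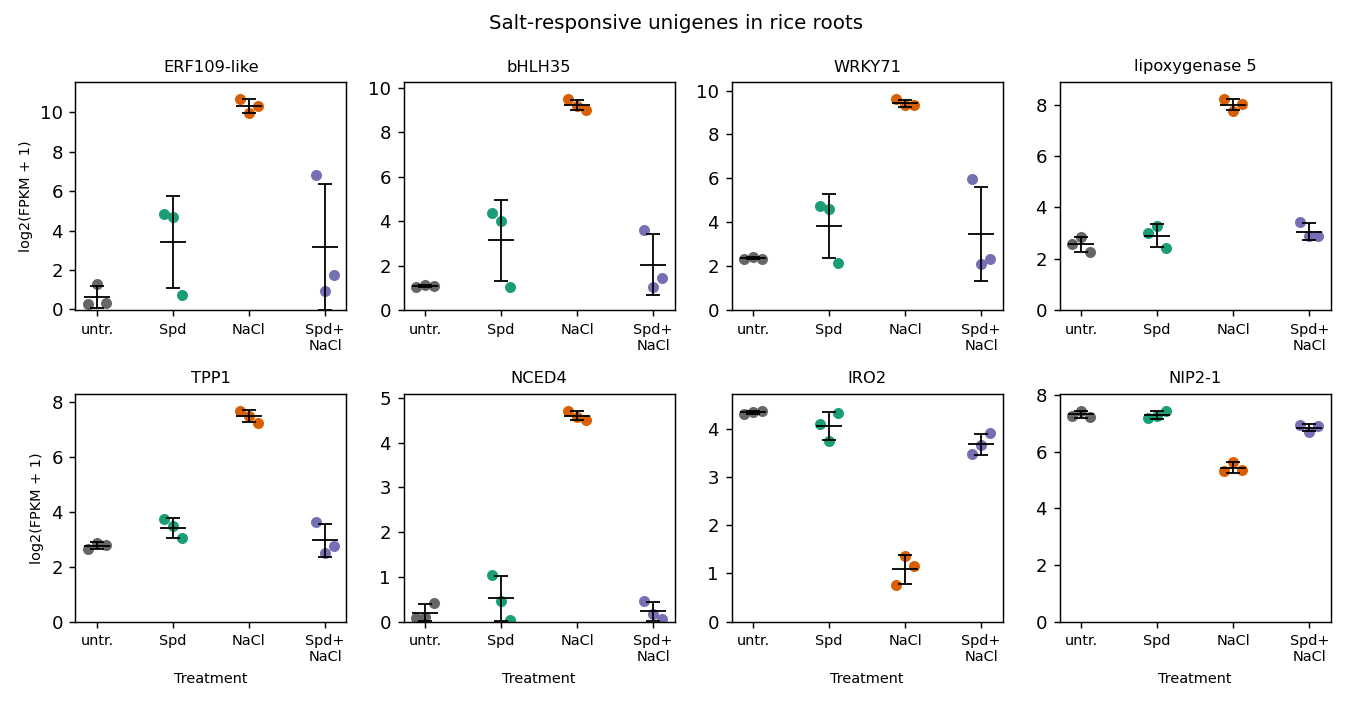
log2(FPKM + 1) of 8 unigenes in each root library by treatment (untr., untreated; Spd, spermidine), with points for libraries and bars for mean ± SD over 3 libraries. ERF109, bHLH35, WRKY71, lipoxygenase 5, trehalose-phosphate phosphatase 1 (TPP1) and NCED4 were highest with NaCl, and IRO2 and a unigene of the aquaporin NIP2-1 (not its most abundant) were lowest there.

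In all, 6586 unigenes were called higher and 8497 lower with NaCl than without treatment, of which 5318 and 6337 were rice hits. The share called higher was 43.7%, and 56.7% with median-ratio scaling, which moved the median log2 change of all unigenes from -0.129 to -0.025. It was 35% among rice-hit unigenes rescaled to the same rice total, where the median was -0.2. The count with a log2 change of at least 1 was 8119. camera called 15 of the 37 lists, fry 30, and camera with an estimated correlation 0 (6 at an unadjusted p below 0.05). In other splits of the same libraries, camera called up to 14 lists at the preset correlation.

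Few rice-hit unigenes were called with spermidine alone. Of 43487 tested, 64 were higher and 68 lower, and a fit of these unigenes alone called 18. In the simulation of this comparison, 0% of rice hits changed by 0.5 on the log2 scale and 30% at 1 were recovered. Many changes of these sizes could therefore be missed. The simulation changed fewer unigenes than were called in the real comparison, so it does not fix the share. NPF5.10, of a nitrate and peptide transporter family, fell from 24.3 ± 3.2 to 9.09 ± 0.627 FPKM (log2 change -1.32 ± 0.16, adjusted p = 0.00134, and 0.0302 in the fit of rice hits alone). Peroxidase 15 went from 101 ± 6.74 to 212 ± 38.3 FPKM (adjusted p = 0.00722). Peroxidase 1 went from 16 ± 6.64 to 41.2 ± 3.26 FPKM, MYB20, a MYB transcription factor, from 3.26 ± 0.407 to 11.4 ± 0.378, and a phenylalanine ammonia-lyase from 16.6 ± 0.704 to 26 ± 2.48. These 4 calls were lost in the fit of rice hits alone (limma adjusted p = 0.125, 0.18, 0.224 and 0.258). The calls of Peroxidase 1 (limma adjusted p = 0.0535 without untreated replicate 1), MYB20 (0.0788 without spermidine replicate 3) and phenylalanine ammonia-lyase (0.129 without spermidine replicate 3) were also lost when those libraries were left out. With only the groups compared in the fit, those of Peroxidase 1 (0.0908) and phenylalanine ammonia-lyase (0.0659) were also lost. Among 73 polyamine unigenes, limma called 0 with spermidine alone (0 adjusted over the list alone, 8 at an unadjusted p below 0.05), and arginine decarboxylase 1 stood at 86.4 ± 9.63 FPKM, ornithine decarboxylase at 5.01 ± 0.321 and the first S-adenosylmethionine decarboxylase unigene at 85 ± 9.94.

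Most calls with spermidine alone lay outside the rice hits. Of 1347 unigenes called higher and 335 lower, 472 and 75 had another plant as best hit, 278 and 46 an organism that is not a plant, and 533 and 146 no hit. A unigene described as sucrose synthase 6, with a best hit outside plants, was at 0.143 ± 0.248 FPKM in untreated roots and 245 ± 131 with spermidine. It was listed at 0 in every NaCl library. A kinesin described as KIN-8B, also with a best hit outside plants, was at 0.113 ± 0.155 and 164 ± 76.5 FPKM, and an aldolase with another plant's best hit at 0.613 ± 1 and 43 ± 18.1. The summed FPKM of the 278 unigenes with hits outside plants was 163 ± 119 in untreated roots, 4970 ± 1210 with spermidine, 72 ± 19.2 with NaCl and 320 ± 119 with both treatments.

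camera called 0 of the 37 lists for spermidine alone (4 at an unadjusted p below 0.05), and fry and camera with an estimated correlation called 0 (3 and 0 at an unadjusted p below 0.05). Among ribosomal proteins, 158 were higher and 9 lower of 1788 (283 and 35 adjusted over the list alone), and 4 and 2 of the 448 with rice hits. The heat shock list had 21 higher and 1 lower of 509 (21 and 2 adjusted over the list alone), and 0 and 0 of the 352 with rice hits. The total of 1682 calls fell to 562 with plant hits alone, 274 at a mean of 5 FPKM or more and 985 without spermidine replicate 3. It was 918 with only the groups compared in the fit.

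Spermidine under salt lowered the unigenes that salt had raised most. bHLH35 fell from 612 ± 102 FPKM with NaCl to 4.63 ± 5.61 with spermidine+NaCl, a log2 change of -7.22 ± 0.83 (adjusted p = 0.000304). A unigene described as ERF109, different from the first, fell from 885 ± 161 to 22.8 ± 36.3 FPKM, a cytochrome P450 from 216 ± 21.1 to 1.84 ± 1.97 and ERF4, an ethylene-response factor, from 182 ± 11.7 to 3.39 ± 4.85. With spermidine+NaCl, the first ERF109 unigene was at 113.51 FPKM in replicate 1 and at 0.92 and 2.36 in the others. The largest rises were in unigenes with another plant as best hit, such as an actin-depolymerizing factor from 1.09 ± 0.401 to 74.1 ± 46.7 FPKM. Root ferredoxin-NADP reductase, a rice hit named after its values were seen, rose from 0.98 ± 1.06 to 11.1 ± 5.19.

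Of the lists called higher with salt, camera called some lower and did not call 5 others. WRKY factors had 76 lower and 13 higher of 160 (83 and 20 adjusted over the list alone), with a median log2 change of -0.65 (camera adjusted p = 8.37e-14; adjusted p = 0.231 with an estimated correlation); WRKY76 fell from 33 ± 4.01 to 1.47 ± 1.07 FPKM. Jasmonate genes had 52 lower and 7 higher of 125 (54 and 9 adjusted over the list alone; camera adjusted p = 2.66e-12; adjusted p = 0.0556 with an estimated correlation), with lipoxygenase 5 falling from 259 ± 39.7 to 7.49 ± 2.03 FPKM and TIFY 6b from 92.5 ± 1.43 to 25.6 ± 3.44. The AP2/ERF and DREB list had 71 lower and 25 higher of 220 (87 and 31 adjusted over the list alone; camera adjusted p = 4.93e-07; adjusted p = 0.247 with an estimated correlation). Pathogenesis-related proteins had 74 lower and 16 higher of 354 (79 and 24 adjusted over the list alone; camera adjusted p = 5.6e-05; adjusted p = 0.0556 with an estimated correlation), and germin-like protein 2-1 fell from 59.1 ± 11.5 to 0.173 ± 0.151 FPKM. The lignin list had 61 lower and 19 higher of 231 (64 and 32 adjusted over the list alone), with a mean log2 change of -0.56 but a median of 0.06, which turned to -0.09 with median-ratio scaling (camera downward, adjusted p = 0.000605; adjusted p = 0.277 with an estimated correlation). A phenylalanine ammonia-lyase fell from 472 ± 39.6 to 153 ± 9.63 FPKM. On the first principal component of rice hits, spermidine+NaCl replicate 1 lay toward the NaCl libraries, at 17.7 against -46.38 and -36.95 for replicates 2 and 3. Its correlation with the NaCl libraries over rice hits was 0.902 to 0.912, against 0.84 to 0.872 for the others. Without it, camera called 14 lists in place of 12.

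The lists not called were wall-loosening proteins, glutathione S-transferases, cellulose and pectin genes, class III peroxidases and NAC factors. Wall-loosening proteins had 24 higher and 15 lower of 169 (28 and 16 adjusted over the list alone), with a median log2 change of 0.14, which turned to -0.03 with median-ratio scaling (camera adjusted p = 0.975). Glutathione S-transferases had 6 higher and 12 lower of 128 (the same adjusted over the list alone; camera downward, adjusted p = 0.183). Cellulose and pectin genes had 19 higher and 27 lower of 257 (20 and 27 adjusted over the list alone), with a median of 0.08, a mean of -0.1 and a downward test (camera adjusted p = 0.216); the median was -0.06 and the adjusted p 0.0491 with median-ratio scaling. Class III peroxidases had 30 higher and 34 lower of 352 (39 and 35 adjusted over the list alone), with a median of 0.14, which turned to -0.02 with median-ratio scaling, and a mean of -0.06 (camera downward, adjusted p = 0.644, and upward after quantile normalization, adjusted p = 0.894). NAC factors had 23 higher and 39 lower of 180 (35 and 45 adjusted over the list alone), with a median of 0.05, which turned to -0.05 with median-ratio scaling, and a mean of -0.3 (camera downward, adjusted p = 0.0576).

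Osmolyte genes had 28 lower and 12 higher of 118 (31 and 20 adjusted over the list alone), with a median of 0, which was -0.15 with median-ratio scaling, and a mean log2 change of -0.39 (camera adjusted p = 0.00217; adjusted p = 0.125 with an estimated correlation); trehalose-phosphate phosphatase 1 fell from 177 ± 26.6 to 7.22 ± 3.57 FPKM. The abscisic acid list had 21 lower and 11 higher of 87 (24 and 17 adjusted over the list alone), with a median of 0.01, which turned to -0.14 with median-ratio scaling and -0.03 after quantile normalization, and a mean of -0.32 (camera downward, adjusted p = 0.0175; adjusted p = 0.456 with an estimated correlation). NCED4 fell from 23.3 ± 1.73 to 0.18 ± 0.178 FPKM. LEA proteins had 7 lower and 0 higher of 20 (the same adjusted over the list alone), with a median of 0.04, which turned to -0.13 with median-ratio scaling, and a mean of -0.53 (camera downward, adjusted p = 0.0155; adjusted p = 0.492 with an estimated correlation). SENESCENCE-ASSOCIATED GENE 21 fell from 145 ± 34.6 to 14.3 ± 5.74 FPKM. Shoot markers had 2 lower and 1 higher of 39 (the same adjusted over the list alone; camera downward, adjusted p = 0.00729; adjusted p = 0.687 with an estimated correlation).

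More iron and water channel genes were called higher than lower against salt alone, while the cell cycle result depended on scaling and on the unigenes included. The iron list had 34 higher and 1 lower of 111 (48 and 1 adjusted over the list alone), with a median log2 change of 0.47 (camera adjusted p = 4.93e-07; adjusted p = 0.247 with an estimated correlation); IRO2 rose from 1.15 ± 0.438 to 12 ± 1.99 FPKM. Aquaporins had 19 higher and 1 lower of 86 (21 and 1 adjusted over the list alone; camera adjusted p = 0.00371; adjusted p = 0.237 with an estimated correlation). A unigene of NIP2-1, the silicon channel of rice roots, was at 160 ± 12.7 FPKM in untreated roots, 42.8 ± 5.83 with NaCl and 115 ± 9.92 with both. A more abundant one was at 2130 ± 136, 1110 ± 103 and 1450 ± 98.2. Cell cycle genes had 32 higher and 10 lower of 314 (26 and 10 adjusted over the list alone; camera adjusted p = 0.0218; adjusted p = 0.687 with an estimated correlation), but 10 higher and 12 lower with median-ratio scaling (camera adjusted p = 0.0685). Among rice hits fitted alone, 25 cell cycle unigenes were higher and 10 lower of 213, and camera did not call the list (adjusted p = 0.0822). Cyclin-D5-1 rose from 40.7 ± 5.8 to 87.6 ± 5.26 FPKM. Organelle-encoded genes, the check of RNA quality, had 12 higher and 0 lower of 165 by limma (4 and 0 adjusted over the list alone, 42 at an unadjusted p below 0.05), but 5 higher and 1 lower with median-ratio scaling. camera did not call the list (adjusted p = 0.362), while fry called it upward (adjusted p = 0.0146). Its median log2 change of 0.14 was near the 0.136 of all unigenes, so the fry call may only reflect the common shift. In the fit of rice hits alone, 17 were higher and 0 lower of 116 (39 at an unadjusted p below 0.05).

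Some polyamine unigenes raised by salt were lower with spermidine+NaCl, while the polyamine list was not called. Ornithine decarboxylase fell to 9.04 ± 1.15 FPKM (log2 change -1.31 ± 0.17, adjusted p = 0.000693), arginine decarboxylase 1 to 87.4 ± 14.7, the first S-adenosylmethionine decarboxylase unigene to 88.2 ± 33.8, the first polyamine oxidase 2 unigene to 15.5 ± 2.45 and the putrescine hydroxycinnamoyltransferase 3 unigene raised by salt to 16.9 ± 3.27. The other unigene of that transferase was at 17.5 ± 4.92 FPKM (adjusted p = 0.0183). This call was lost without NaCl replicate 2 or 3 or spermidine+NaCl replicate 1 (highest adjusted p = 0.0731, without NaCl replicate 3). The second polyamine oxidase 2 unigene was at 44.4 ± 2.27 (adjusted p = 0.042), against 52.8 ± 1.06 with NaCl and 33.6 ± 1.87 untreated. Its call was lost after quantile normalization (0.135) and when any library other than untreated replicate 2 and spermidine replicate 2 was left out (highest adjusted p = 0.129, without NaCl replicate 3). The polyamine transporter PUT1 was at 8.47 ± 0.416 FPKM in untreated roots, 13.1 ± 1.7 with NaCl and 11.7 ± 0.0351 with both (adjusted p = 0.501 against NaCl). Spermidine synthase 1 was at 101 ± 1.35 FPKM (adjusted p = 0.252). Of 73 polyamine unigenes, 9 rose and 13 fell (11 and 13 adjusted over the list alone), with a median log2 change of 0.06, which turned to -0.08 with median-ratio scaling, and a mean of -0.1 (camera downward, adjusted p = 0.357). The potassium transporter HAK7 fell from 7.43 ± 1.39 to 0.73 ± 0.608 FPKM. HKT8 was at 23.2 ± 4.74 (log2 change 0.68 ± 0.2, adjusted p = 0.0427), a call lost with median-ratio scaling, quantile normalization or without NaCl replicate 3 (adjusted p = 0.121).

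**Figure D3:**
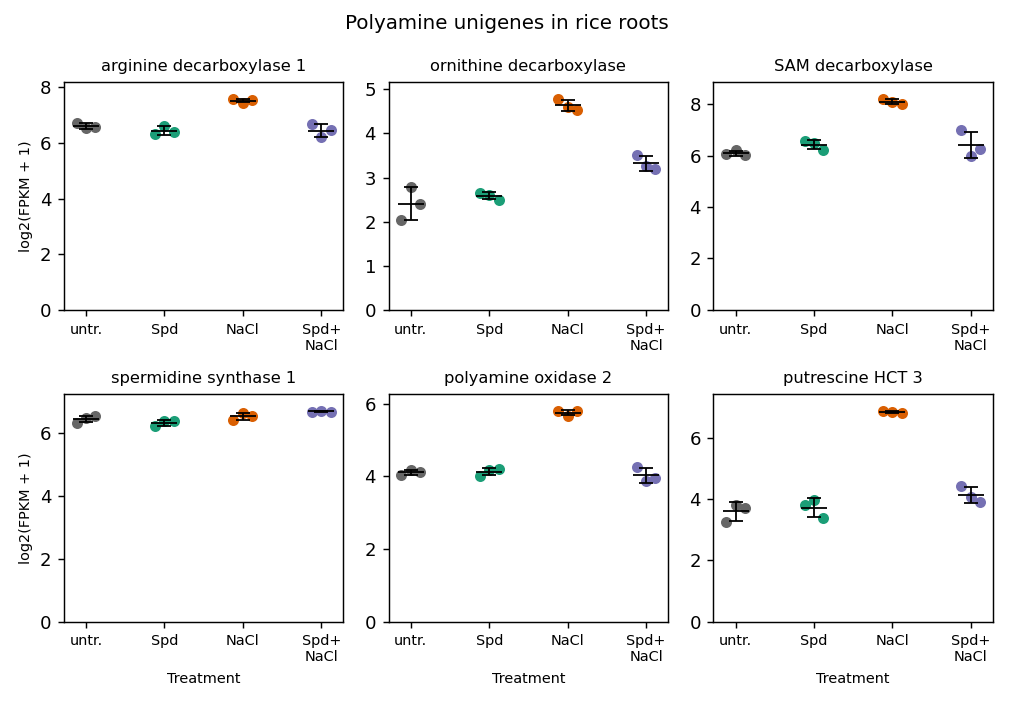
log2(FPKM + 1) of 6 polyamine unigenes in each root library by treatment (untr., untreated; Spd, spermidine; SAM, S-adenosylmethionine; HCT, hydroxycinnamoyltransferase), with points for libraries and bars for mean ± SD over 3 libraries. The plotted unigene of each name is the one with the lowest adjusted p for NaCl; those of the 3 decarboxylases, polyamine oxidase 2 and putrescine hydroxycinnamoyltransferase 3 were highest with NaCl, some other unigenes of the same names were not, and spermidine synthase 1 was not called with NaCl (adjusted p = 0.545) or between spermidine+NaCl and NaCl (adjusted p = 0.252).

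**Figure D4:**
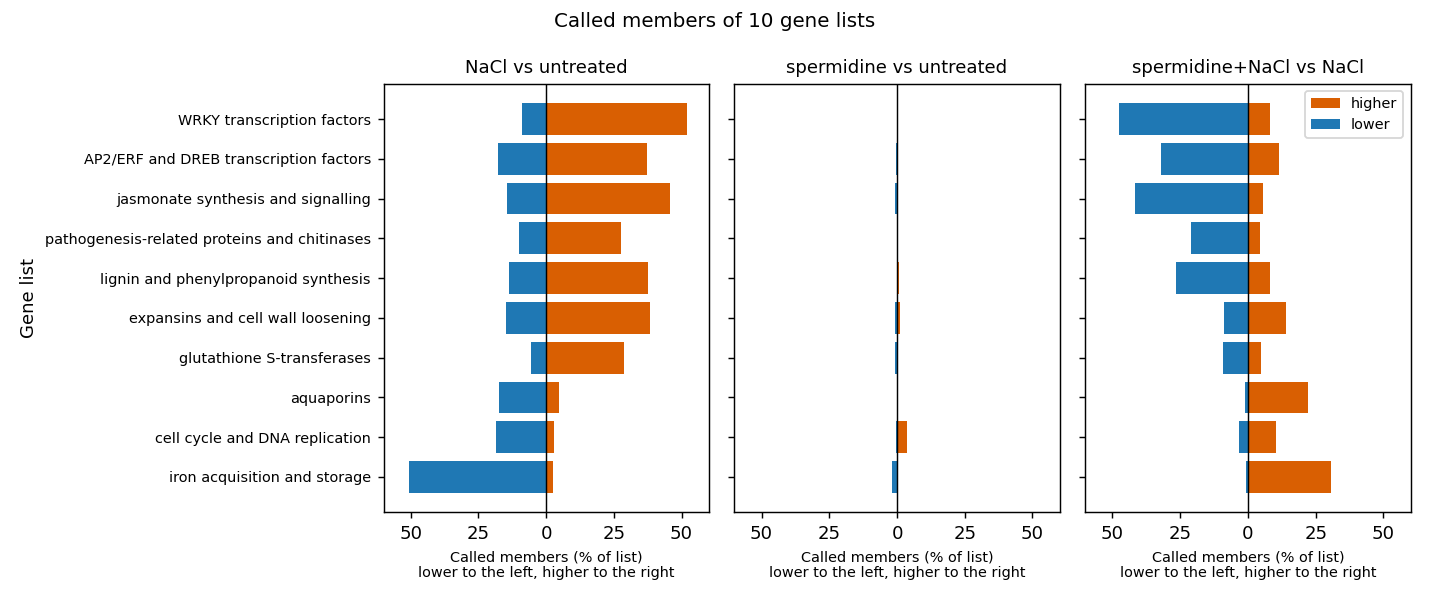
Percent of the members of 10 gene lists called higher (to the right) and lower (to the left) by limma in 3 comparisons of rice roots. With NaCl, 83 of 160 WRKY unigenes were higher and 56 of 111 iron unigenes lower; with spermidine+NaCl against NaCl, 76 WRKY unigenes were lower and 34 iron unigenes higher, and cell cycle calls changed from 32 higher and 10 lower to 10 and 12 with median-ratio scaling.

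With spermidine+NaCl, 5679 unigenes were higher and 4724 lower than with NaCl, of which 4508 and 3793 were rice hits. The share called higher was 54.6%, and 33% with median-ratio scaling, which moved the median log2 change from 0.136 to 0; it was 66.5% among rescaled rice hits, with a median of 0.22. Lower calls outnumbered higher ones when some libraries were left out, with shares higher of 46.3% without NaCl replicate 1, 47.2% without NaCl replicate 3, and 44.9% and 49.4% without spermidine+NaCl replicates 2 and 3. With only the groups compared in the fit, 3279 were higher and 4198 lower. The count was 5297 at a log2 change of at least 1, 6270 without NaCl replicate 1, 6629 without NaCl replicate 3 and 6657 without spermidine+NaCl replicate 2. camera called 12 of the 37 lists, fry 25, and camera with an estimated correlation 0 (6 at an unadjusted p below 0.05). Another split of the same libraries gave 13 lists with camera at the preset correlation.

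Of the 15083 unigenes called with NaCl, 7907 were also called in the opposite direction with spermidine under NaCl and 39 in the same direction. Independent lists would share 472.6 unigenes going up then down and 732.9 going down then up; the data held 4218 and 3689. Across unigenes, which are not independent, the changes had r = -0.591 and a covariance of -0.539. Simulated unchanged groups gave -0.5 and -0.12, because both comparisons use the NaCl libraries. Among rice hits the covariance was -0.644 against -0.0499 simulated. With 3 NaCl libraries these could not be split into parts of at least 2 libraries, so part of the excess may come from sharing them. Of the 11655 rice-hit unigenes called with NaCl, 94.6% moved toward the untreated level, with a median absolute log2 change of 0.93 with NaCl and 0.26 remaining with spermidine+NaCl. The remaining median was 0.34, 0.18 and 0.2 in the 3 spermidine+NaCl libraries. The count of 7907 was 4093 at a log2 change of at least 1 and 5179 without NaCl replicate 1.

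NaCl and spermidine against untreated shared 290 unigenes called in the same direction and 23 in opposite directions, with 134.7 up and 43.2 down in common for independent lists against 32 and 258 in the data. The changes had r = 0.264 and a covariance of 0.23, where simulated unchanged groups against the same untreated libraries gave 0.501 and 0.12. In the fit of rice hits alone the shared calls were 7. The 290 became 1204 without a filter on low values, 173 with a pseudocount of 0.1, 178 without untreated replicate 1, 184 without spermidine replicate 2 and 140 without spermidine replicate 3.

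Both treatments together left 1569 unigenes higher and 1969 lower than in untreated roots, of which 1117 and 813 were rice hits. The less abundant of these NIP2-1 unigenes, bHLH35 and lipoxygenase 5 stood at 115 ± 9.92, 4.63 ± 5.61 and 7.49 ± 2.03 FPKM, against 160 ± 12.7, 1.12 ± 0.0436 and 4.99 ± 1.22 untreated. Among the rice hits called with NaCl, 1424 were still called in the same direction. The total of 3538 was 2192 at a log2 change of at least 1, 1889 with only the groups compared, 1377 without untreated replicate 1, 2112 without untreated replicate 2 and 1645 without spermidine+NaCl replicate 2.

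Against spermidine alone, spermidine+NaCl gave 1712 higher and 2848 lower unigenes, of which 1426 and 831 were rice hits. Of 542 called unigenes with hits outside plants, 489 were lower with both treatments. Among them was sucrose synthase 6, at 245 ± 131 FPKM with spermidine and 0.05 ± 0.0866 with both. The share higher was 62.7% in the fit of rice hits alone and 52.5% after rescaling them. The total of 4560 was 8606 without a filter on low values, 2052 with rice hits alone, 2424 without spermidine replicate 1, 2598 without spermidine replicate 3 and 2932 without spermidine+NaCl replicate 2.

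The change with spermidine differed with and without NaCl for 7152 unigenes, 2752 with a positive and 4400 with a negative interaction. The share positive was 38.5%, 21.7% with median-ratio scaling and 53.5% among rescaled rice hits. The putrescine hydroxycinnamoyltransferase 3 unigene raised by salt had an interaction of -2.84 ± 0.27 on the log2 scale (adjusted p = 0.000235), the first S-adenosylmethionine decarboxylase unigene -2.01 ± 0.3 (adjusted p = 0.00219) and ornithine decarboxylase -1.5 ± 0.25 (adjusted p = 0.00396): each was lowered by spermidine under NaCl, with no call for spermidine alone. The other unigene of the transferase had an interaction of 1.42 ± 0.63 (adjusted p = 0.199).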

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

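The tests of depth, of a spermidine effect on other organisms and of handling were chosen only after the results they address were seen, as were the control in the test of RNA of other organisms and the counts of shared calls in the test of roots without salt.

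The effect of spermidine differed with and without NaCl for 7152 unigenes, by the interaction term. The most negative interactions on the log2 scale were ERF109 (-9.91, and -9.26 for a second unigene), bHLH35 (-9.28 and -7.73), sucrose synthase 6 (-7.51) and WRKY28 (-7.48), and the most positive were serine carboxypeptidase II-2 (4.35), an acyl-CoA-binding protein (4.3, listed at 0 in every spermidine library), ribosomal protein L37a (3.54), actin-2 (3.5), cyclic dof factor 1 (3.16) and ribosomal protein S27-2 (3.1). The calls of the second ERF109 unigene, the carboxypeptidase, L37a, the dof factor and S27-2 ended with a pseudocount of 0.1, and that of the carboxypeptidase also with median-ratio scaling. Those of the carboxypeptidase, L37a, actin-2, the dof factor and S27-2 also ended without NaCl replicate 1, with adjusted p of 0.105, 0.0847, 0.0621, 0.0904 and 0.0746. Of 100 drawn splits that reassigned spermidine within salt status, 2 gave as many unigenes, the real split included, and the highest other gave 7241. These splits reassign spermidine both with and without salt, so they cannot exclude chance for the interaction itself. The 8 other splits that kept the NaCl and spermidine+NaCl libraries apart gave 3445 to 7241, against 7152 for the real split. The remaining splits gave at most 726, so the count rests mainly on the difference under salt.

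Unigenes without an Oryza best hit made up 1283 of the 1347 called higher with spermidine alone, and 278 of them name an organism that is not a plant. Greater depth does not account for this, since the relative depth of the spermidine libraries was 1.06 times that of the untreated ones. RNA of other organisms in the libraries, from the cultures or by carry-over of reads between libraries, which was not tested, is a candidate source that stays open: in spermidine+NaCl replicate 2, the library of its group with the most FPKM outside plants, the 1005 called unigenes with another plant's hit or no hit had a median log2 difference of 0 to the other libraries. The bound set beforehand against this source, a difference no larger than that of rice hits (0.01), was met, but it was wrong: the 278 unigenes with hits outside plants themselves differed by 0.05 there, so that single library could not show the source. Whether spermidine raised such organisms or cultures differed cannot be told apart, since the share of FPKM outside plants was 1.03% to 1.85% with spermidine and 0.768% to 1.64% without (exact permutation p = 0.2, two-sided; 0.1 is the smallest possible with 3 libraries each).

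Most unigenes changed by NaCl moved back toward the untreated level with spermidine under NaCl. Chance values of single NaCl libraries do not account for it. Unigenes called from the other NaCl libraries still moved back by a median of 0.55 or more on the log2 scale against each held-out one. A deviation common to all 3 NaCl libraries, as from a shared culture, would also be in the held-out one, so the test does not cover it. Scaling does not account for the move back, as 6735 unigenes moved back with median-ratio scaling against 7907 without it. Among rescaled rice hits 9015 did, against 7556 without rescaling. Roots that met no salt would not share the salt response, yet of the rice hits called for NaCl both without and with spermidine, which share no library, 1217 went the same way and 49 opposite (295.5 and 309.4 for independent lists); the correlation across unigenes, with a bound of 0.2 set beforehand, was 0.219, but 0.0383 without spermidine+NaCl replicate 1 and 0.104 without spermidine replicate 3, while same-direction calls were over 2 times the opposite ones with any library left out, and weaker exposure stays open. A harvest or handling difference of the NaCl libraries cannot be told apart from salt, since all 3 lay outside the range of the others on the first component; a lasting effect of spermidine on the salt response may also account for the pattern.

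The 3-against-3 comparisons have 10 splits each, too few for a share under 0.05. The real counts and the highest of the other splits were 15083 and 9 for NaCl against untreated, 1682 and 39 for spermidine, 10403 and 11 for spermidine+NaCl against NaCl, 3538 and 8 against untreated, and 4560 and 201 against spermidine. For lists, the real counts and highest others were 15 and 14 for NaCl, 0 and 10 for spermidine and 12 and 13 for spermidine+NaCl against NaCl. Splits that mixed the groups could thus give nearly as many list calls as the real split, or more. The number of lists called by camera at the preset correlation therefore does not set the treatments apart from other groupings. Of 100 drawn splits, 1, the real one, gave as many as the 7907 unigenes moved back (highest other 6), and 1 as many as the 290 shared by NaCl and spermidine (highest other 24). These splits do not show an overlap beyond chance. The calls per comparison in the drawn splits were not counted, so their few shared unigenes may only reflect few calls.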

How the results depend on the processing

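The analyses limited to rice hits and rescaled rice hits, with their lists under left-out libraries and median-ratio scaling, were chosen after seeing the data, and the other alternatives before. No called change of a named gene reversed under the alternatives run for it, and the interaction count stayed within 1.5 times of 7152 (4782 to 8618 over 25 alternatives). Of 741 pairs of a named gene and a setting, 688 kept the call or its absence, 50 lost a call, in 22 of 111 genes and comparisons, and 3 gained one. The split of calls did turn: the share higher went from 43.7% to 56.7% for NaCl and from 54.6% to 33% for spermidine+NaCl against NaCl with median-ratio scaling, and to 56.1% and 33.2% at a log2 change of at least 1. For spermidine+NaCl against NaCl it was also 40.5% without a filter, 49.9% without a variance trend and 44.9% to 49.4% with NaCl replicate 1 or 3 or spermidine+NaCl replicate 2 or 3 left out, and 3279 were higher and 4198 lower with only the groups compared in the fit. Against untreated it went from 44.3% to 54% at a mean of 5 FPKM or more, 51.3% with plant hits, 57.6% with rice hits, 51.1% with rescaled rice hits and 50.1% without spermidine+NaCl replicate 1, and against spermidine from 37.5% to 56.4%, 50.3%, 62.7% and 52.5% in the first 4 of these. The positive share of interactions went from 38.5% to 50.8% at a mean of 5 FPKM or more and 53.5% with rescaled rice hits. The cause of these turns was not tested. Medians of several lists changed sign with scaling, as given beside them. The other results moved by over 1.5 times as follows, and where no construction is named the cause was not tested. Asking for a log2 change of at least 1, a stricter rule, gave 8119 calls for NaCl, 5297 for spermidine+NaCl against NaCl, 2192 against untreated, 2822 against spermidine and 4093 moved back. Without a filter, calls were 6364 for spermidine, 8606 for spermidine+NaCl against spermidine and 1204 shared by NaCl and spermidine; at a mean of 5 FPKM or more they were 274, 2711 and 28. A pseudocount of 0.1 gave 173 shared. Plant hits alone, which are fewer unigenes, gave 562 for spermidine and 93 shared. Rice hits alone gave 18 for spermidine, 1933 for spermidine+NaCl against untreated, 2052 against spermidine and 7 shared, and rescaled 18, 1757, 1776 and 7. With only the groups compared in the fit, which has fewer samples, calls were 918 for spermidine, 1889 for spermidine+NaCl against untreated and 2458 against spermidine. For lists, an estimated correlation gave 0 and fry 30 for NaCl, and 0 and 25 for spermidine+NaCl against NaCl; rice hits alone gave 4 lists for spermidine. With each library left out, counts ran from 985 to 1771 for spermidine (lowest without spermidine replicate 3), 6270 to 10853 for spermidine+NaCl against NaCl, 1377 to 3937 against untreated, 2424 to 4867 against spermidine, 5179 to 7829 moved back, 140 to 305 shared and 0 to 1 lists for spermidine (1 without spermidine replicate 3).

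Deviations of same-numbered libraries correlated at -0.109 to 0.147, above 0.1 in 2 of 18 pairs. Those of libraries with different numbers correlated at -0.1 to 0.098, above 0.1 in 0 of 36 pairs. Among rice hits, 1 of 18 and 3 of 36 pairs were above 0.1. No strong pairing by replicate number was seen, but these values cannot show whether same-numbered libraries were handled together. With the replicate number as a block, calls were 14155, 1588, 9700, 3355 and 4001 in the 5 comparisons (NaCl, spermidine, spermidine+NaCl against NaCl, untreated and spermidine), 6113 for the interaction, 7272 moved back and 235 shared, with 14, 0 and 13 lists; among named genes the block ended the interaction call of cyclic dof factor 1 and that of the second polyamine oxidase 2 unigene for spermidine+NaCl against NaCl (adjusted p = 0.063). Depth is known only as a ratio between libraries, so how far it limits low unigenes cannot be given.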

Other observations

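The list tests of the comparisons of spermidine+NaCl with untreated and with spermidine, the genes named for them, the library values of NAC2 and WRKY71 and the list tests on rice hits alone, with their alternatives, were chosen only after results were seen.

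Wall-loosening genes were higher with salt in roots given spermidine too. Against untreated roots, spermidine+NaCl had 48 wall-loosening unigenes higher and 1 lower of 169 (61 and 8 adjusted over the list alone; camera adjusted p = 2.93e-10; adjusted p = 0.236 with an estimated correlation), and against spermidine alone the numbers were also 48 and 1 (64 and 3 adjusted over the list alone; camera adjusted p = 5.26e-12; adjusted p = 0.2 with an estimated correlation). Expansin-A31 was at 0.327 ± 0.325 FPKM (SD, n = 3) in untreated roots, 1.03 ± 0.265 with spermidine, 10.2 ± 1.36 with NaCl and 9.67 ± 0.594 with both, and Expansin-B18 at 2.74 ± 0.224, 1.28 ± 0.362, 7.08 ± 0.356 and 10.7 ± 2.13. Expansins loosen cell walls during growth. Lignin genes had 35 higher and 6 lower of 231 against untreated (50 and 9 adjusted over the list alone; camera adjusted p = 8.26e-06; adjusted p = 0.236 with an estimated correlation). The Casparian strip and suberin list is named for barriers that seal the root's inner layers, but also takes in GDSL esterases by description. Whether those serve the barriers was not checked. The list had 26 higher and 5 lower of 250 against untreated (42 and 9 adjusted over the list alone, camera adjusted p = 0.000344, and 0.0495 with an estimated correlation). Against spermidine it had 18 higher and 9 lower (39 and 12 adjusted over the list alone, camera adjusted p = 0.00395, and 0.136 with an estimated correlation). With NaCl alone 34 were higher and 35 lower (35 and 37 adjusted over the list alone; camera adjusted p = 0.332), and the difference between these list results was not tested. The xylem and phloem list, a check of tissue makeup, was higher too, with 6 higher and 2 lower against untreated (9 and 2 adjusted over the list alone; camera adjusted p = 0.0311, and 0.0681 after quantile normalization; adjusted p = 0.335 with an estimated correlation) and 5 and 4 against spermidine (8 and 4 adjusted over the list alone; camera adjusted p = 0.00833, and 0.0541 after quantile normalization; adjusted p = 0.232 with an estimated correlation). Of the suberin list, omega-hydroxypalmitate O-feruloyl transferase, a suberin enzyme, was at 43.6 ± 3.42 FPKM in untreated roots, 54.3 ± 6.93 with spermidine, 80.4 ± 8.26 with NaCl and 113 ± 12.3 with both. GDSL esterase/lipase LIP-4 of the same list went the other way, at 136 ± 9.28, 103 ± 15.3, 72.9 ± 10.4 and 62.9 ± 5.61 FPKM in the same order.

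Cytokinin genes were lower with both treatments. With NaCl alone the list was not called by camera (adjusted p = 0.167), with 38 lower and 16 higher of 103 (44 and 18 adjusted over the list alone), a median log2 change of -0.29 and a mean of -0.04, while fry called it downward (adjusted p = 2.74e-05); the difference from both treatments was not tested. Against untreated roots, spermidine+NaCl had 12 lower and 0 higher of 103 (20 and 3 adjusted over the list alone; camera adjusted p = 0.00273; adjusted p = 0.0495 with an estimated correlation), and against spermidine 13 lower and 0 higher (20 and 0 adjusted over the list alone; camera adjusted p = 0.0015; adjusted p = 0.0771 with an estimated correlation). The cytokinin-activating enzyme described as LOGL3 was at 23.4 ± 2.53 FPKM in untreated roots, 27.7 ± 4.7 with spermidine, 9.32 ± 0.575 with NaCl and 10.1 ± 0.446 with both. The response regulator ORR4, which cytokinin induces, was at 88.2 ± 12.3, 83.7 ± 7.11, 50.1 ± 3.15 and 52.8 ± 2.32 FPKM.

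In rice hits alone, the ribosomal protein list was lower with spermidine than in untreated roots (448 members, median log2 change -0.15, camera adjusted p = 1.68e-06; adjusted p = 0.756 with an estimated correlation). However, limma called 2 members higher and 0 lower there (83 at an unadjusted p below 0.05). The list was higher with spermidine+NaCl than with NaCl (117 members higher and 2 lower, median 0.27, camera adjusted p = 1.61e-05; adjusted p = 0.59 with an estimated correlation), as 17 of 116 organelle-encoded genes, the check of RNA quality, also were by limma, with 0 lower (39 at an unadjusted p below 0.05). The organelle-encoded list can share members with the ribosomal list, since both match ribosomal proteins of organelles, so it is not an independent check. Both camera calls of the ribosomal list held with median-ratio scaling (medians -0.13 and 0.11) and with each library left out. NAC, WRKY and osmolyte lists had medians of 0.14, 0.14 and 0.09 with spermidine alone there (camera adjusted p = 0.00366, 0.00517 and 0.0383; adjusted p = 0.662, 0.756 and 0.662 with an estimated correlation). limma called 0 of their 177, 156 and 107 rice-hit members (14, 9 and 10 at an unadjusted p below 0.05). The camera calls of all 3 lists ended without spermidine replicate 1 (adjusted p = 0.1, 0.162 and 0.1) and without untreated replicate 3 (0.0737 each). Those of WRKY and osmolytes ended without spermidine replicate 2 (0.083 each), and that of osmolytes without untreated replicate 1 (0.144) or spermidine+NaCl replicate 2 (0.0523). Spermidine replicates 1 and 2 stood at -32.47 and -29.06 on the first principal component of rice hits and replicate 3 at -68.25, against -65.95 to -58.9 in untreated roots. NAC2 was at 124.83, 159.3 and 56.32 FPKM and WRKY71 at 25.39, 22.94 and 3.38 in spermidine replicates 1, 2 and 3.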
